A study of Mus musculus with 4 samples.

How the data were processed

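RNA was measured in 4 libraries of primary cultured mouse astrocytes, 1 for each combination of OASIS genotype label (wild type or deficient) and treatment label (untreated or doxorubicin). Doxorubicin was given at 1 µg/ml for 1 h to cultures past confluence, which were collected 24 h later, per the labels' protocols. Libraries were made with a SMART-Seq v4 kit, which does not mark strand, per the labels' protocols. The authors deposited 1 table per library with an estimated count and a TPM value (scaled by transcript length and library size) for each gene, per the file headers. DRAGEN and the mouse build GRCm38 are named per the submitters' processing notes, and the software version, the annotation release and the read filters are not given in the sources used here. The deposited counts are not normalized and contain fractions in 5810 to 6451 genes per library, and they were rounded to whole numbers for use as counts. The deposited TPM values sum to the same total in each library, per the file headers and the values, and were used only as an alternative scale.

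Each table held the same 55487 gene identifiers. Symbols, chromosomes and coordinates came from a GENCODE annotation of GRCm38, matched by identifier without its version; 55227 matched and 260 did not. Total counts ran from 17481188 to 22559613. The 10 most abundant genes took 6.76 to 7.21% of the counts and mitochondrially encoded genes 0.9 to 1.1%. With 3 counts taken as the upper limit that a count of 0 allows, the floor was 0.131 to 0.174 CPM after TMM scaling. Ratios of a gene between libraries have exact conditional binomial 95% intervals. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

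Groups followed the genotype and treatment labels of each sample, and the libraries are called by those labels throughout. The number in each title follows the treatment and marks no replicate. Counts were scaled to CPM with the TMM factors of edgeR (0.98 to 1.02), and 1 CPM was added before each log2 ratio, which understates the change of low genes. A gene counted as higher or lower by size when its log2 ratio was at least 1 or at most -1 and its mean over the 4 libraries was at least 1 CPM. There were 4 such comparisons of single libraries and the difference of both doxorubicin responses, all without p-values since each group holds 1 library and no replicate. Additive models of genotype and treatment were fitted to the counts of all 4 libraries with edgeR's quasi-likelihood test, and Benjamini-Hochberg adjusted p of at most 0.05 were called. These models have 1 residual degree of freedom, which holds the dependence of the response on genotype together with noise, and their p-values measure only the spread among these libraries. The common dispersion was 0.0863, and the spread of a gene was moderated with 14.3 prior degrees of freedom.

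The gene lists were written before the data were examined, as were the tests, the rule for naming genes and the alternatives, except where a choice is stated to have been made afterwards. There were 22 lists: p53 targets, genes reported to be regulated by OASIS, extracellular matrix, unfolded protein response, secretory vesicle transport, mitosis, DNA replication, DNA repair and checkpoint, senescence secretome, interferon response, reactive astrocyte, cholesterol synthesis, nuclear envelope, mitochondrially encoded genes, a sex chromosome check, and markers of astrocytes, microglia, the oligodendrocyte lineage, neurons, fibroblasts and meninges, endothelium and pericytes, and ependyma. The median log2 ratio of each list was set against 10000 random lists of the same size, drawn from 20 bins of mean expression, as a description of these libraries. The additive fits were also tested with camera, with a preset correlation of 0.01 and with an estimated one. Genes were named by rule: the 10 highest and 10 lowest log2 ratios among genes that met the rule of size with a mean of at least 5 CPM, the 10 with the smallest p in each direction of an additive test, up to 4 members of each list with the largest absolute ratio, and always Creb3l1 and Cdkn1a. Unnamed transcripts and pseudogenes were counted and not named, and a few genes that met the rule are not reported here.

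On simulated counts for the additive doxorubicin test, drawn for 15596 genes with 100 genes changed 2-fold and 100 changed 4-fold, edgeR recovered 37 and 71 of them, each with the right sign, beside 12 false calls. Other genes were changed 4-fold with genotype. No simulated response depended on genotype, so the simulation does not cover genes whose responses differ by genotype. The alternatives were DESeq2 size factors, total counts, pseudocounts of 0.5 and 5 CPM, a minimum mean of 5 CPM, no minimum, and TPM, and for the additive tests DESeq2, limma-voom and a model without the other factor. A repeat without the genes on X and Y was added after the data were examined. Software was R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Reads were not analysed here, so counts per exon of Creb3l1 were not used here.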

Results

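RNA sequencing measured gene expression in primary cultured mouse astrocytes that the labels give as OASIS wild type or OASIS deficient. OASIS is the product of Creb3l1, a transcription factor held in the membrane of the endoplasmic reticulum until its N-terminal part is released to the nucleus. Cultures were left untreated or received doxorubicin, a topoisomerase II poison that breaks DNA, at 1 µg/ml for 1 h and were kept for 24 h afterwards. The series asks how loss of OASIS alters gene expression during the DNA damage response. There were 4 libraries, 1 for each combination of genotype and treatment, so no difference between single libraries has a replicate check. The total counts were 19518653 for wild type untreated, 22559613 for wild type with doxorubicin, 17481188 for deficient untreated and 20171539 for deficient with doxorubicin. Of the genes counted, 15596 had a mean of at least 1 CPM (counts scaled to library size) over the 4 libraries and entered the comparisons. A count of 0 allowed at most 0.131 to 0.174 CPM (3 counts), and all intervals on single genes are 95% exact binomial intervals that cover counting error only.

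Creb3l1 itself (ENSMUSG00000027230.9, GRCm38 chromosome 2, 91982328 to 92024502, minus strand) was lower in both libraries labelled deficient and was absent from neither. The counts were 966 in wild type untreated, 636 in wild type with doxorubicin, 260 in deficient untreated and 235 in deficient with doxorubicin, or 48.5, 27.8, 15.1 and 11.9 CPM. The deficient level was 31.1% of wild type without treatment (27.1 to 35.8%) and 42.8% with doxorubicin (36.7 to 49.8%). These counts cover the whole gene, so they do not show which exons the remaining reads come from.

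Genes of the sex chromosomes divided the libraries by treatment label. Xist, the RNA that silences the second X chromosome in female cells, had 2547 and 2742 counts in the wild-type and deficient libraries labelled doxorubicin, against 1 and 0 in the libraries labelled untreated. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 353 to 1567 counts in wild type untreated, 366 to 868 in deficient untreated and 0 in both libraries labelled doxorubicin. Treatment label and sex of the culture therefore cannot be separated in any comparison of doxorubicin with untreated.

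**Figure D1:**
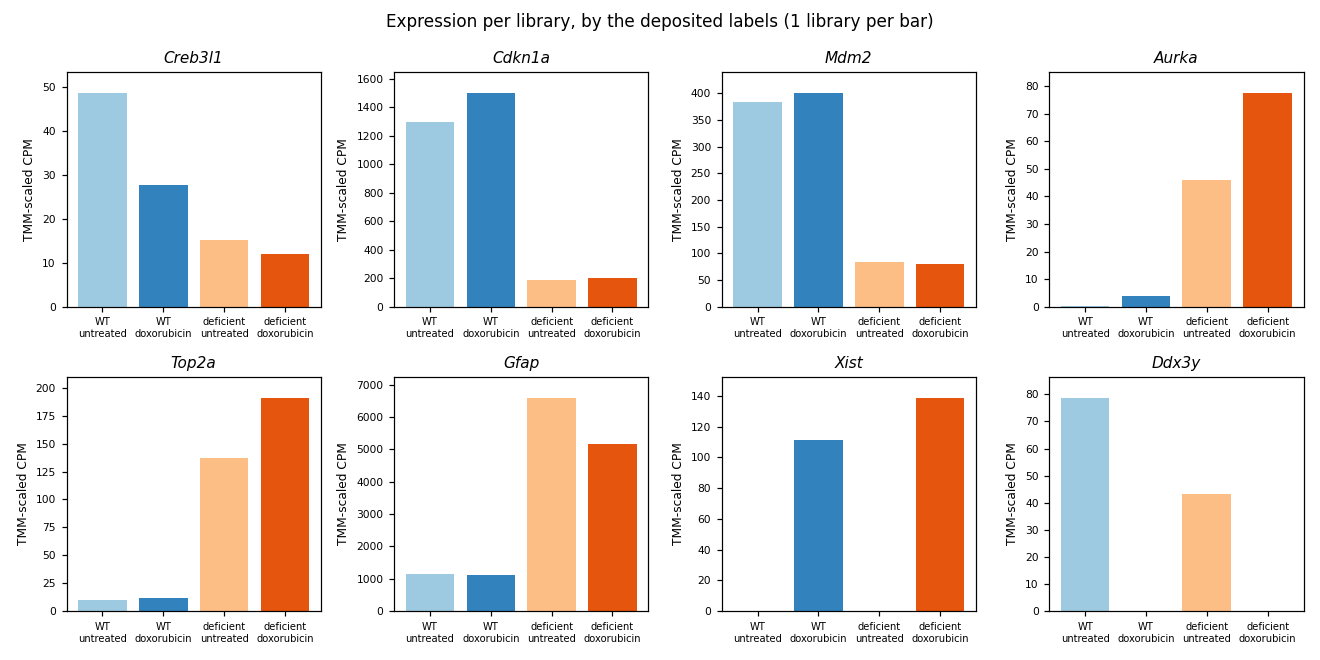
TMM-scaled CPM of 8 genes in the 4 libraries, 1 bar per library, named by genotype and treatment label. Cdkn1a and Mdm2 are high in the wild-type libraries, Aurka, Top2a and Gfap in the deficient libraries, and Xist and Ddx3y divide by treatment label, with Ddx3y at 0 in both doxorubicin libraries.

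The first comparison asks which genes differ after doxorubicin in astrocytes labelled wild type. The known targets of p53, the transcription factor activated by DNA breaks, had a median log2 ratio of 0.09 over 32 genes, at percentile 89.9 of random lists matched on expression, and none of the 32 differed by at least 2-fold. Cdkn1a, which encodes the cell cycle inhibitor p21, had 34221 counts with doxorubicin and 25804 without, a log2 ratio of 0.21. Markers of microglia, the macrophages of the brain, had a median of -0.49 (percentile 0), with 15 of 16 below 0 and 0 of 16 at least 2-fold lower. Examples are Trem2 at -0.83, Tmem119 at -0.83 and Cx3cr1 at -0.79. Across all genes, 636 were higher and 850 lower by at least 2-fold, 78 and 106 of them by at least 4-fold.

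Outside Xist and its antisense partner Tsix (6 against 525 counts), whose reads cannot be told apart without strand, the highest ratios belonged to genes of low count in the untreated library. Postn, a secreted matrix protein, went from 2 counts to 219, a ratio of 95.2 (26.1 to 792), and Zfpm2 from 33 to 443 (log2 ratio 2.94). Cyp4f14, Foxred2 and Ctf1 had log2 ratios of 2.63, 2.57 and 2.52. Inpp5j had 2 and 121 counts, a ratio of 52.6 (14.3 to 440). Zcchc12, on the X chromosome, had 0 and 106, at least 30.7-fold higher. Brca1, a DNA repair gene, had 5 and 123 counts (log2 ratio 2.35). Below Y-linked genes, the lowest ratios were those of Exosc6, a subunit of the RNA exosome with 185 counts untreated and 0 with doxorubicin (at least 70.9-fold lower), Nfam1 (-2.85), Wdr62 (-2.84), Zfp641 (-2.61) and Car8 (-2.50). Kif2c, a mitotic kinesin, had 91 counts untreated and 0 with doxorubicin, at least 34.9-fold lower.

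The matrix genes went both ways in this pair. Postn and Dcn (1.51) were higher while Col3a1 (-1.48) and Lox (-1.46) were lower, with a list median of -0.17 over 32 genes (percentile 0.41). The list of genes reported to be regulated by OASIS had a median of -0.44 (7 measured, percentile 0.04), led by Col1a2 at -0.94 and Chst3 at 0.89. Fibroblast and meningeal markers had a median of -0.37 and oligodendrocyte lineage markers one of -0.40, with Pdgfra, a receptor of oligodendrocyte precursors, at -1.59. Mitosis genes had a median of 0.23 over members from -2.48 (Kif2c) to 1.76 (Aurka). DNA repair genes (median 0.04), interferon response genes (0.17), ependymal markers (0.40) and the 13 mitochondrially encoded genes (0.15) lay inside the central 95% of random lists.

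In the libraries labelled deficient, the doxorubicin comparison held fewer large differences. Again no p53 target differed by 2-fold, and their median was 0.15 (percentile 99.9), with Cdkn1a at 0.09 (3204 counts untreated, 3926 with doxorubicin). Genes of mitosis had a median of 0.50, with 30 of 30 above 0 and 0 of 30 at least 2-fold higher. Aurkb, the kinase of the chromosomal passenger complex, was at 0.94 and Cenpf, a kinetochore protein, at 0.82. DNA replication genes had a median of 0.32 and DNA repair genes one of 0.21 (percentiles 100 and 99.0), with Cdc45 at 0.88 and Fancd2 at 1.08. Microglia markers had a median of -0.66, with 16 of 16 below 0 and 2 of 16 at least 2-fold lower. The reactive astrocyte list had a median of -0.29, with 28 of 33 below 0 and 2 of 33 at least 2-fold lower. Its lowest members were Ptgs2, the inducible cyclooxygenase, at -1.61 and Serpina3n, a secreted protease inhibitor, at -1.51. The senescence secretome list had a median of -0.33 over 17 genes (percentile 0.01), with Ereg at -1.15 and Ccl2 at -0.85. In the wild-type pair its median was -0.26 (percentile 2.34).

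By size, 246 genes were higher and 301 lower in this pair, 5 and 15 of them by at least 4-fold. Apart from Xist and Tsix (12 and 550 counts), the highest were Pcdh18 (1.98), Psd4 (1.92), Synj2 (1.88), Rab11fip1 (1.83), Zfp442 (1.52) and Nnt (1.49), the last a symbol that 2 gene IDs share. Ppl had 1 and 56 counts, a ratio of 48.7 (8.40 to 1959), and Jag2, a Notch ligand, had 3 and 48, a ratio of 13.9 (4.49 to 69.9). Below the Y-linked genes came Tns2 (-2.17), Cyp1a1 (-1.92), Spon2 (-1.85), Pde2a (-1.77), Zfp94 (-1.73) and Gpr176 (-1.73).

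Whether the response depended on OASIS was addressed by the difference of both responses, deficient minus wild type. Since no p53 target differed by 2-fold in either labelled pair, this cannot show under these labels whether a p53 response depends on OASIS. The p53 targets had a median difference of -0.05 (percentile 22.8), which became 0.01 on the deposited TPM values, which are scaled by transcript length, and Cdkn1a differed by -0.11 (0.07 on TPM). Of the 22 lists, 5 had a median difference outside the central 95% of random lists, without adjustment for the number of lists. They were mitosis at 0.32 (percentile 99.7, 6 of 30 at least 2-fold up and 1 down), the oligodendrocyte lineage at 0.47 (98.8, 2 of 12 up), genes reported to be regulated by OASIS at 0.38 (99.4, 0 of 7), extracellular matrix at 0.21 (99.4, 2 of 32 up and 3 down) and reactive astrocyte at -0.25 (0.04, 2 of 33 down). Among the genes with the widest differences, Wdr62, a spindle pole protein, stood at 4.13, Synj2 at 3.69, Zfp641 at 3.24 and Nek2, a centrosomal kinase, at 2.92, while Postn stood at -3.95 and Apol9b at -2.68. Apcdd1 had 9 and 114 counts in wild type against 387 and 220 in deficient. Inpp5j and Ctf1 differed by -2.63 and -2.54. Exosc6, Ttc39c and Gen1 followed at 2.79, 2.72 and 2.72, and Slc2a13, Zbtb48 and Brca1 at -2.52, -2.48 and -2.47. The difference was at least 1 in 1194 genes and at most -1 in 943. Across all genes the labelled responses had a Pearson correlation of 0.09 and a Spearman correlation of 0.04, and genes are not independent replicates. There were 29 genes higher in both (10.0 by chance), 58 lower in both (16.4 by chance) and 77 in opposite directions (25.7 by chance). The chance figure takes all genes as equally variable and all these counts exceed it, so the excess does not show opposed responses. Without the genes on X and Y, a choice made after the data were seen, the Pearson correlation was 0.05.

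The additive test of doxorubicin takes each genotype as a pair of libraries and leaves 1 residual degree of freedom. At an adjusted p of at most 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3 genes were higher and 22 lower with doxorubicin. An unadjusted p under 0.05 was reached by 864 of 15596. Besides Xist, Tsix and the Y-linked genes, the calls were led by Serpina3n, which fell by 1.59 on the log2 scale (SE 0.0944, adjusted p 9.94e-08 by edgeR). Its counts were 26574 and 9589 in wild type and 20660 and 8305 in deficient. Also lower were the chitinase-like gene Chil1 by 0.67, the macrophage lysozyme Lyz2 by 0.57, the transthyretin gene Ttr by 0.93 and the iron-binding lipocalin Lcn2 by 0.71, with adjusted p from 0.000563 to 0.00264. Of the microglia markers 2 fell, or 9 adjusted over the list alone, and of the reactive astrocyte list 2 fell, or 3 adjusted over the list alone. Of the mitosis genes 0 passed over all genes and 10, all higher, passed adjusted over the list alone. No p53 target passed either way. In camera, a test of whether a list ranks apart from other genes, with its preset correlation of 0.01, the lists past an adjusted p of 0.05 were microglia markers (9.81e-21, down), mitosis (1.62e-17, up), reactive astrocyte (2.13e-11, down), sex chromosome genes (2.54e-09, down), DNA replication (4e-05, up), p53 targets (0.00318, up), fibroblast markers (0.0405, down) and extracellular matrix (0.0465, down), the last pair against medians of 0.07 and 0.02 in deficient. None of these held with an estimated correlation, where the lowest adjusted p by camera was 0.599. That version rests on the 1 residual degree of freedom and could hardly pass any list, so it does not count against them. Among these lists the estimated correlation ran from -0.2 for sex chromosome genes to 0.473 for fibroblast markers, with -0.0161 for mitosis and 0.2 for microglia markers. The estimates rest on the same residual degree of freedom, so they do not check the preset 0.01, on which the adjusted p above depend. Without the genes on X and Y, 0 genes were higher and 13 lower (819 at an unadjusted p under 0.05). Without genotype in the model no gene passed (100 at an unadjusted p under 0.05).

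The comparison of deficient with wild type without treatment gave far larger differences, and the p53 targets and the cell cycle genes led them. Of 32 p53 targets, 25 were at least 2-fold lower in the library labelled deficient, with a median log2 ratio of -1.99 or 3.96-fold. Pmaip1, which encodes the pro-apoptotic protein NOXA, had 4782 counts in wild type and 89 in deficient (-5.29). Perp, an apoptosis-linked junction protein, was at -4.02, the receptor gene Eda2r at -3.84, Trp53inp1 at -3.53 and Cdkn1a at -2.79 (25804 against 3204 counts). All 30 mitosis genes were at least 2-fold higher in deficient, with a median of 3.51 or 11.4-fold. Aurkb had 0 counts in wild type and 1139 in deficient, at least 439-fold higher, Aurka had 8 and 792 (5.07), Cenpf was at 4.93 and Ube2c, a subunit of the mitotic ubiquitin ligase machinery, at 4.63. With the mitosis genes at 0 counts set to their bound, the median stayed at 3.51.

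Genes of DNA synthesis were also higher in the untreated deficient library. DNA replication genes had a median of 1.86, with 26 of 30 at least 2-fold higher, led by Tk1 (3.43), Mcm5 (3.14), Cdc6 (2.71) and Prim1 (2.59). DNA repair genes had a median of 0.83, with Brca1 at 3.64 and Exo1 at 2.82. Among single genes outside the lists, Pimreg (0 and 931 counts, at least 359-fold), Iqgap3 (0 and 590, at least 228-fold), Clspn (0 and 385, at least 148-fold), Pclaf (4.53), Shcbp1 (4.45) and Ckap2l (4.42) were highest. At the other end, St14, the membrane serine protease matriptase, had 1935 counts in wild type and 0 in deficient, at least 557-fold lower. Gsta1, a glutathione transferase, had 1833 and 24 (-5.28), Ckmt1, a mitochondrial creatine kinase, 1138 and 4 (-5.56), and Acaa1b 758 and 19 (-4.22). Gsta1, Ckmt1 and Acaa1b have near-identical relatives that can share reads, so their values are uncertain. Robo3 (371 and 0, at least 107-fold), Slc4a11 (-4.20) and Pou3f1 (-3.94) were also among the lowest.

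Secreted and immune genes of the senescence secretome had a median of -1.04 in the untreated deficient library, with the chemokine Cxcl1 at -3.64 and the stress cytokine Gdf15 at -2.46. Interferon response genes had a median of -0.61, with Xaf1 at -1.56 and Oasl2 at -1.55. Cholesterol synthesis genes had a median of 0.57, with Mvd at 1.67. Cell type markers moved with the genotype label as well. Astrocyte markers had a median of 0.71, with Gfap, the intermediate filament of astrocytes, at 2.53 (22712 against 113415 counts), and neuron markers one of 1.04, with Dcx at 2.34. Oligodendrocyte lineage markers had a median of 1.73, with 12 of 12 above 0 and Mobp at 3.28 and Sox10 at 2.75. With their members at 0 counts set to the bound that median was 2.01, and Mbp, an abundant myelin gene, had 109 CPM in deficient against 21.5 in wild type. Microglia markers had a median of 0.09 (-0.23 on TPM), fibroblast and meningeal markers -0.23, endothelial and pericyte markers -0.53 and ependymal markers 0.43, none outside the central 95% of random lists. The reactive astrocyte list (-0.06), the extracellular matrix (-0.17), the unfolded protein response (0.19, and -0.04 on TPM), secretory vesicle transport (-0.02), the nuclear envelope (0.12, and -0.12 on TPM) and the genes reported to be regulated by OASIS (-0.22) also lay within it. The nuclear envelope list held 1 exception, Lmnb1, the lamin B1 gene, at 3.44. Mitochondrially encoded genes had a median of 0.43, with 13 of 13 above 0. In all, 1527 genes were higher and 1588 lower by at least 2-fold. On the deposited TPM, where the median of all genes shifted to -0.20, the split was 1221 to 2095.

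With doxorubicin, the p53 targets had a median of -1.94 in deficient over wild type, with 24 of 32 at least 2-fold lower, among them Pmaip1 (6197 and 97 counts, -5.52), Perp (-3.92), Gdf15 (-3.59), Eda2r (-3.39) and Cdkn1a (-2.91). Mitosis genes had a median of 3.87, with 30 of 30 at least 2-fold higher. Aurkb had 0 and 2526 counts, at least 975-fold, Kif2c 0 and 1021, at least 394-fold, and Plk1, the kinase that drives mitotic entry, was at 5.33. DNA replication genes had a median of 2.11, with Cdc45 at 3.72 and Lig1, the replicative DNA ligase, at 3.42. DNA repair genes had a median of 0.86, with Exo1 at 3.52 and Fancd2 at 2.81. Lmnb1 was at 3.07. Pimreg had 3 and 1561 counts, a ratio of 602 (206 to 2924), and Iqgap3 had 2 and 1260, a ratio of 729 (202 to 6029). Kif20a (5.08), Nek2 (5.42), Cdca3 (4.98), Ndc80 (4.95) and Ckap2l (4.80) were also among the highest.

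The lowest genes with doxorubicin overlapped those without it. St14 had 2795 counts in wild type and 2 in deficient, a ratio of wild type to deficient of 1207 (334 to 9973), and Robo3 had 527 and 2, a ratio of 228 (62.7 to 1884). Gsta1 (-5.50), Ckmt1 (-4.67), Acaa1b (-4.32), Cited4 (-4.65), Ppp2r2c (-4.51) and Pm20d1 (-4.17) followed, and Krtap1-5, a keratin-associated gene with close relatives, had 623 and 0 counts (at least 179-fold). The senescence secretome had a median of -1.13, the interferon list -0.36, with Ifit1 at -2.20, cholesterol synthesis 0.47 and the reactive astrocyte list -0.25. Astrocyte markers had a median of 0.73, with Gfap at 2.21 (25639 against 102215 counts), neuron markers 1.16 and oligodendrocyte lineage markers 2.27 (2.82 with 4 members at their bound), with Sox10 at 3.91 and Pdgfra at 3.15. By size, 1670 genes were higher and 1490 lower, and on TPM 1353 and 1795. Both deficiency comparisons, which share no library, correlated across genes at a Pearson coefficient of 0.69 and a Spearman coefficient of 0.61, a calculation chosen after the data were seen. There were 899 genes higher in both (164 by chance), 806 lower in both (152 by chance) and 70 in opposite directions (316 by chance).

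**Figure D2:**
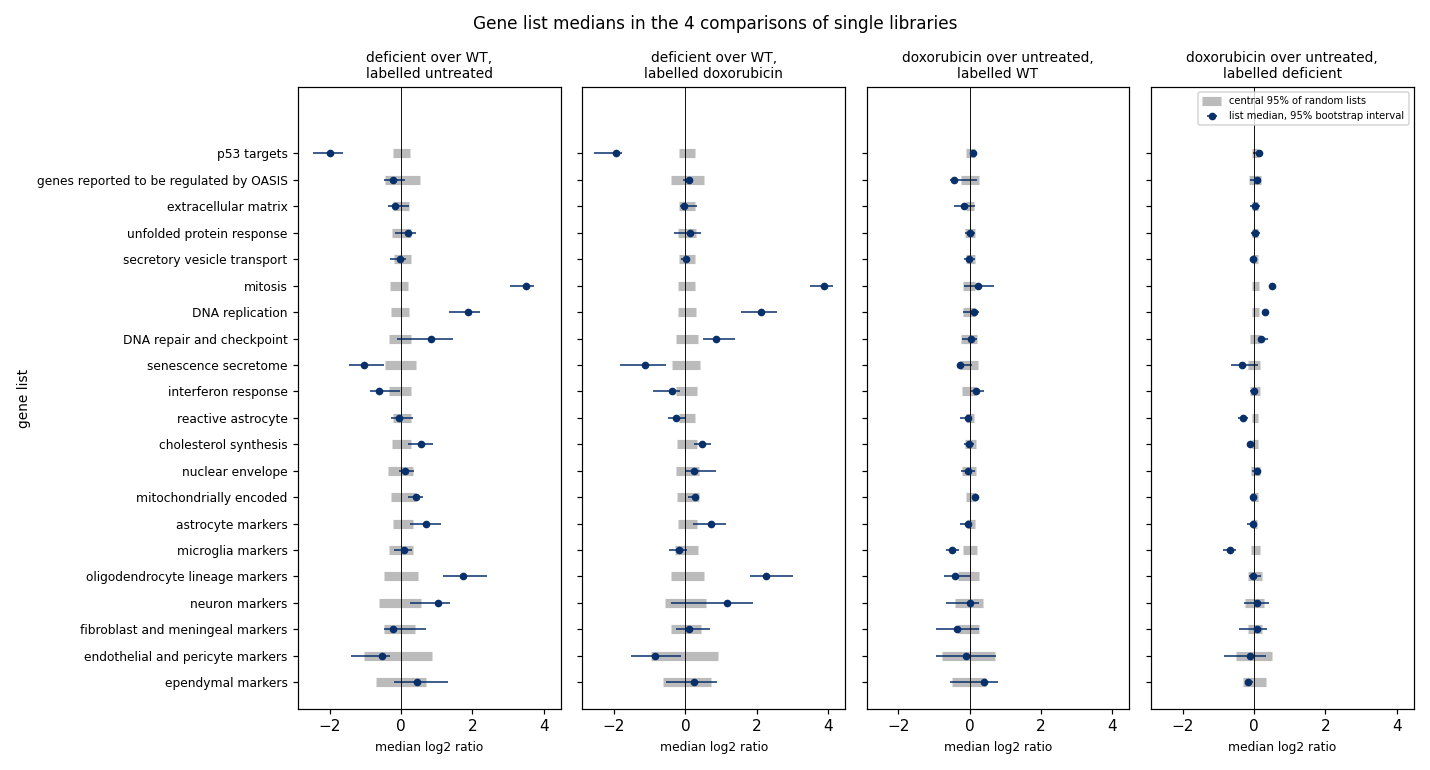
Median log2 ratio of each gene list (points, with 95% bootstrap intervals over genes) in the 4 comparisons of single libraries, against the central 95% of 10000 random lists matched on expression (grey bars). Mitosis genes lie at 3.51 and 3.87 and p53 targets at -1.99 and -1.94 in deficient over wild type, while both lie between 0.09 and 0.50 in doxorubicin over untreated.

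The additive test of OASIS deficiency, with treatment in the model, called 1972 genes higher and 1648 lower in deficient at an adjusted p of at most 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg). Pmaip1 fell by 5.66 on the log2 scale (SE 0.177, adjusted p 2.96e-11 by edgeR) and Cdkn1a by 2.86 (SE 0.0991, adjusted p 6.58e-11). The cyclin gene Ccng1 fell by 2.71, the stress-induced sestrin Sesn2 by 2.79 and the epoxide hydrolase Ephx1 by 1.95. Nqo1 and Srxn1, enzymes of the response to oxidants, fell by 2.66 and 2.55, and the protease inhibitor Serpine2 by 1.73. Gfap rose by 2.37 (SE 0.0841, adjusted p 6.58e-11), the metallothionein Mt2 by 3.32, smooth muscle actin Acta2 by 1.78 and calponin Cnn1 by 3.17. Among genes of division, Ube2c rose by 4.94, Racgap1 by 4.78, Top2a, the topoisomerase that doxorubicin poisons, by 3.91 and Cdk1 by 3.63. The histone gene Hist1h2ap, a member of a family with near-identical copies, had an increase of 2.98 that is uncertain for that reason.

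By list, 25 of 32 p53 targets fell and 1 rose (26 and 1 adjusted over the list alone), and all 30 mitosis genes and 29 of 30 DNA replication genes rose (the same counts adjusted over the list alone). Of the DNA repair genes 13 rose and 1 fell (14 and 2 adjusted over the list alone). Of the senescence secretome 8 of 17 fell and 1 rose (15 and 1 adjusted over the list alone), and of the interferon list 7 fell and 2 rose (8 and 3). Increases were found for 11 of 20 cholesterol synthesis genes, 13 of 20 astrocyte markers, 11 of 12 oligodendrocyte lineage markers, 6 of 11 neuron markers and 6 of 13 mitochondrially encoded genes (11, 14, 11, 7 and 6 adjusted over the list alone, where 2 neuron markers also fell). The extracellular matrix had 6 up and 7 down (7 and 8 adjusted over the list alone), and the reactive astrocyte list had 7 up and 9 down (11 and 10 adjusted over the list alone). In camera with the preset correlation, the adjusted p was 1.51e-50 for p53 targets (down), 1.76e-50 for mitosis (up), 3.17e-29 for DNA replication (up), 4.7e-13 for astrocyte markers (up) and 7.23e-11 for oligodendrocyte lineage markers (up). It was 9.37e-05 for cholesterol synthesis (up), 0.000211 for mitochondrially encoded genes (up), 0.00278 for the senescence secretome (down), 0.00526 for DNA repair (up), 0.00879 for neuron markers (up) and 0.00978 for the interferon list (down). The genes reported to be regulated by OASIS reached 0.0262 (down) with Cdkn1a as the only call over all genes, against a median of 0.11 with doxorubicin. No list held with an estimated correlation, where the lowest adjusted p by camera was 0.428. That version rests on the 1 residual degree of freedom and could hardly pass any list, so it does not count against them. For the lists with an adjusted p above, the estimated correlation ran from -0.0909 for neuron markers to 0.692 for mitochondrially encoded genes. It was -0.0161 for p53 targets, 0.0805 for mitosis, 0.0069 for DNA replication, -0.0421 for astrocyte markers and 0.667 for oligodendrocyte lineage markers. These estimates rest on the same residual degree of freedom. They do not check the preset 0.01, on which the adjusted p with the preset correlation depend.

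**Figure D3:**
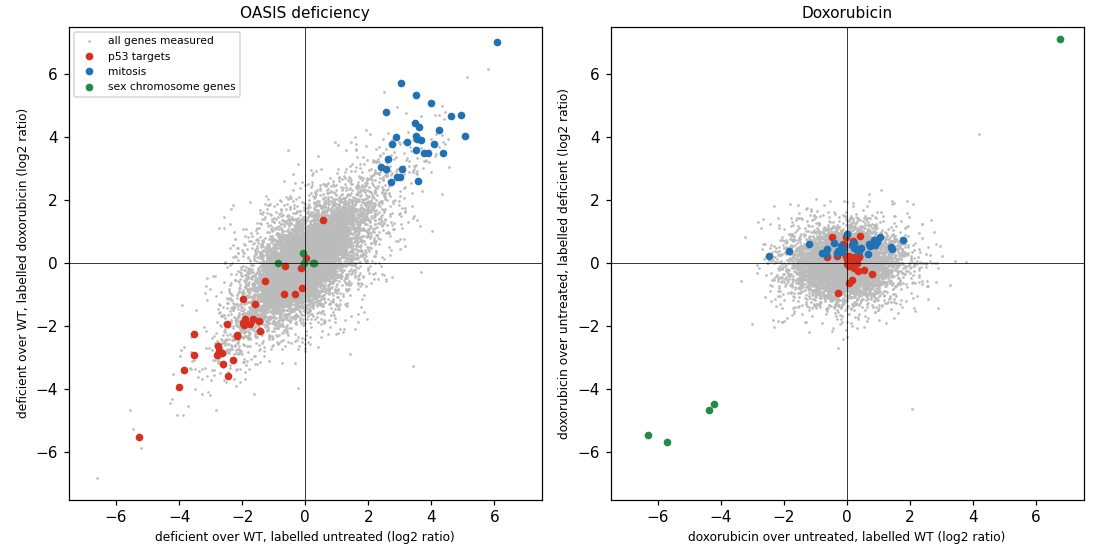
Log2 ratios of all 15596 genes (grey) in both deficiency comparisons (left) and both doxorubicin comparisons (right), 1 point per gene, with 3 gene lists in colour. The deficiency comparisons correlate at 0.69 with p53 targets low and mitosis genes high in both, and the doxorubicin comparisons correlate at 0.09 with the sex chromosome genes far from the rest.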

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

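All tests of explanations in this part were chosen after the result they bear on had been seen. The labelled doxorubicin responses held 77 genes at least 2-fold apart from untreated in opposite directions, each from 1 library per group, and the difference itself was not tested. Among those with the 10 highest and 10 lowest differences, the log2 difference, deficient minus wild type, was 4.13 for Wdr62, 3.69 for Synj2, 3.02 for Tub, 2.88 for Naaladl2, -2.48 for Elf4 and -2.46 for Rftn1. Genes in opposite directions numbered 13 at a minimum mean of 5 CPM and 2 with a pseudocount of 5 CPM, so most of the 77 had low counts.

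The p53 targets were high and the mitosis genes low in both libraries labelled wild type, whatever the treatment label. A doxorubicin effect that followed the labels within both genotypes is argued against by the p53 target medians of doxorubicin over untreated, of which the larger was 0.15 on the log2 scale, small although at percentile 99.9 of random lists. A larger share of oligodendrocyte lineage cells in the deficient libraries is argued against for the p53 targets, since astrocyte markers were not diluted with them (lower end of the interval of the difference in medians 2.16). That share stays open for the mitosis genes. The intervals of lineage markers minus mitosis genes were -2.65 to 0.05 untreated and -2.37 to 0.85 with doxorubicin, mostly below 0 without excluding it. They were computed with medians of 2.12 and 3.75 untreated and 3.25 and 4.04 with doxorubicin, which are larger than the list medians given above. An exchange of the labels of the untreated wild-type and the doxorubicin deficient libraries could give this split, but the values for it are those that prompted the idea and do not test it: p53 target medians along the genotype label, the smaller in size -1.94, and sex chromosome genes that pair the libraries across it. Creb3l1, at 31.1% and 42.8% of wild type in the libraries labelled deficient, follows the labels as given. Under the exchange the same split would lie between doxorubicin and untreated, so it does not decide between the arrangements. OASIS deficiency alone in cultures that did not respond to doxorubicin cannot be told apart from an exchange with 1 library per group. The correlation of both deficiency comparisons (0.693) goes with either. With 1 library per group, neither account can be separated from other differences between the cultures. The difference of the doxorubicin responses would be unchanged by the exchange, since both libraries enter it with the same sign.

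The sex chromosome genes divided the libraries by treatment label with no overlap. Cultures from animals of different sex may be the source, since the highest count of a Y-linked gene or Xist where it should be absent was 1. Under the labels as given, each genotype was then cultured from male cells for the untreated library and from female cells for the doxorubicin library. Under the exchange above, each sex would hold 1 genotype with both treatments. The labels give no sex, so neither arrangement can be checked against them.

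Creb3l1 reads remained in both libraries labelled deficient. Loss of the whole gene is argued against in every library, since the lowest count was 235. An exchange of labels together with a deficient allele that lowers the counts of the gene needs Creb3l1 to be higher with doxorubicin, and it was lower in both pairs (48.5 to 27.8 and 15.1 to 11.9 CPM), with an additive log2 fold change of -0.58 (SE 0.266, p 0.0444 and adjusted p 0.875 over all genes by edgeR; p 0.0116 by limma-voom and 0.103 by DESeq2), so the values go against it without excluding it in every fit. An exchange with an allele that leaves most reads of the gene in place remains open, as does a partial deletion under the labels as given. Counts per exon could decide between them and were not used here.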

How the results depend on the processing

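No called value changed sign under any alternative, although medians near 0 did on TPM (microglia markers in deficiency untreated to -0.23). The causes of the changes below were not tested except where fewer genes or another pseudocount set them by construction. With a pseudocount of 5 CPM, genes higher and lower numbered 83 and 143 for doxorubicin in wild type, 15 and 27 in deficient, 763 and 643 for deficiency untreated, 861 and 629 with doxorubicin, and 306 and 174 for the difference of the responses. With a minimum mean of 5 CPM, which tests fewer genes, they were 244 and 365, 77 and 107, 1015 and 880, 824 lower for deficiency with doxorubicin, and 600 and 387. With no minimum, 1024 were higher for doxorubicin in wild type and 1459 lower in the difference, and with a pseudocount of 0.5 CPM doxorubicin in deficient gave 407 and 456. The additive doxorubicin test gave 22 higher and 56 lower with DESeq2 size factors, 26 and 73 at a minimum mean of 5 CPM, 17 and 67 with limma-voom, 6 higher with DESeq2, 10 lower with no minimum, 0 and 0 without genotype in the model, and, chosen after seeing the data, 0 and 13 without X and Y. The additive deficiency counts stayed within 1.5 times of 1972 and 1648, from 1506 and 1208 with no minimum to 2320 and 1945 with limma-voom. Of the named genes of the additive tests, 12 lost their call without the other factor and 1 with DESeq2. Of list medians under alternatives, 12 moved beyond their bootstrap interval and 863 did not. The additive doxorubicin test is blocked by genotype label. No block by replicate number could be fitted, since each group holds 1 library and the numbers in the titles follow the treatment, and no replicate could be left out. Depth limits what is seen of genes near the floor of 0.131 to 0.174 CPM.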

Other observations

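The gene groups of the first paragraphs here were chosen after single members had been seen, and their lists come from textbook knowledge. Targets of NRF2, the transcription factor of the response to oxidants, were lower in both libraries labelled deficient, with a median log2 ratio of -1.45 in each comparison and 11 of 16 at least 2-fold lower. Slc7a11, the cystine importer that feeds glutathione synthesis, was at -2.76 untreated and -3.05 with doxorubicin, Nqo1 at -2.47 and -2.83, and the glutathione synthesis genes Gclc and Gclm at -1.51 and -1.40 untreated. Contractile genes had medians of 1.43 and 1.51 in deficient over wild type, with 6 and 7 of 10 at least 2-fold higher, among them Cnn1 (3.40 and 2.90), Acta2 (1.86 and 1.70) and Tagln (1.79 and 1.34), while Tpm1 was at 0.61 and 0.56 and Actg2 at 0.18 and 0.04. The metallothioneins Mt1, Mt2 and Mt3, which bind zinc and copper, were all at least 2-fold higher in deficient in both comparisons, with Mt1 at 2.39 and 1.98. Along the doxorubicin labels no member of these groups differed by 2-fold, and the medians ran from -0.22 for metallothioneins in deficient to 0.21 for contractile genes in wild type.

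Replication-dependent histone genes went against the other genes of DNA synthesis. Of 46 measured, 26 were at least 2-fold lower and 9 higher in the untreated deficient library (median -1.21), and 25 lower and 6 higher with doxorubicin (median -1.29). Hist1h2ac was at -3.19 and -3.31, Hist1h4h at -2.51 and -2.76 and the linker histone Hist1h1c at -1.36 and -1.46, while Hist1h2ap was at 2.91 untreated. Most transcripts of these genes end without a poly(A) tail in dividing cells, and the kit used here primes on poly(A), so the counts can show the tailed form alone. Members of this family share near-identical sequence, and their single values are uncertain.

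The effect of gene length was the only test of an explanation here planned before its result was seen. Doxorubicin poisons topoisomerase II, and a loss of transcripts of long genes in the libraries labelled wild type would have raised long genes in deficient over wild type. Under the labels as given, a library of each genotype received doxorubicin. The prediction therefore applies only if both libraries labelled wild type were treated, as under the exchange above. The Spearman correlation across 13635 genes between the log2 ratio and the genomic span was -0.01 untreated and 0.09 with doxorubicin, where a value above 0.1 in both had been predicted. The prediction was not met. Whether doxorubicin lowers long genes in these cells was not measured apart from the labels, so this does not decide on the exchange. With exon length, which the prediction did not cover, these correlations were -0.124 untreated and 0.007 with doxorubicin. Along the doxorubicin labels the correlation with genomic span was -0.12 in wild type and 0.06 in deficient. In the wild-type pair the median log2 ratio was -0.09 for the 2051 genes longer than 100 kb and 0.10 for the 3230 shorter than 10 kb. Its correlation with exon length was -0.17, larger in size than with genomic span, and the deficient pair (0.08 with exon length) did not share this trend. Each pair compares single libraries that differ in sex as well as in treatment label, and the source of the trend was not tested.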
